A study of Homo sapiens with 12 samples.

How the data were processed

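According to the sample labels, the 12 arrays hold 2 lines without and with decitabine, 3 arrays in each of 4 groups, from Trizol RNA labelled as biotin cRNA. The labels do not say what untreated cells received, or whether adriamycin was present during treatment. Nothing in the labels says that replicates came from separate cultures, so the p-values measure only the spread between these samples. The values are log2 intensities as deposited by the authors, and how background, summarization and normalization were done before that is not given in the sources used here. No further scaling was applied.

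Of 33297 transcript clusters, 19460 carry 1 gene symbol per the platform annotation, 1754 carry several and 12083 carry none. Of the clusters with 1 symbol, 19429 matched a RefSeq gene by its Entrez identifier, and gene order is that of GRCh38.p14. The brightest cluster stood for each of 18417 genes, 769 of which had more than 1 cluster and 16900 of which are protein-coding. Clusters without exactly 1 name, and globin and HLA members without a cluster of their own, were left out of the gene comparisons, and the clusters without exactly 1 name were tested apart.

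Group means over the 12 arrays were fitted in limma 3.58.1 (R 4.3.3) with moderated variances (8 residual and 4.71 prior degrees of freedom) and Benjamini-Hochberg adjusted p. Gene lists, written down before the data were examined together with the comparisons, thresholds and rules for naming genes, were tested with camera at a preset correlation of 0.01 over 28 lists. Alternatives were a correlation estimated per list, and fry. Adjusted p for lists are over the 28 lists, and counts of members are those of the tests over all genes unless adjusted over the list alone is stated. Genes are named by the size of their change, by list membership or because they were fixed in advance. Some list members with small p were left unnamed, after the results were seen, because their calls were lost with single arrays left out. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

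In 20 simulations with 200 changed genes each, the fit found 74.2% (untreated lines), 75.3% (decitabine in KA) and 78.2% (decitabine in KS) of changes of 0.5 on the log2 scale. Of changes of 1 it found 99.6, 99.4 and 99.6%. False calls made up 4.73, 5.18 and 5.22% of calls. The number of arrays limits the precision.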

Results

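Gene expression was measured on Affymetrix arrays in 2 human leukaemia cell lines, each without and with decitabine. KS is K562, an established line from a chronic myeloid leukaemia, and KA is K562/ADR, its subline selected for resistance to adriamycin (doxorubicin, an anthracycline) and maintained in 50 nM of that drug. Decitabine is a deoxycytidine analogue that is built into DNA and traps DNA methyltransferases there, and it was given at 5 nM for 72 hours. Each of the 4 groups (untreated KS, treated KS, untreated KA, treated KA) held 3 arrays, a number that limits the precision. The declared purpose was to learn how decitabine acts on multidrug resistance that rests on P-glycoprotein, the efflux pump encoded by ABCB1. The line and the adriamycin in its medium differ together between KA and KS. Values were on a log2 scale from 0.226 to 13.2, array medians lay between 4.96 and 5.01, and arrays of a group correlated at 0.990 to 0.995 across transcript clusters. For every gene named below for the size of its change between 2 groups, each array of one group lay above each array of the other; for the difference of responses this was not asked. All changes below are on the log2 scale with the standard error (SE), and a gene is called higher, lower, raised or lowered at an adjusted p under 0.05 over the 18417 genes tested. A group mean of at most 3.39, the highest lower quartile of an array, was not shown to exceed background, and the size of a change from or to it is a lower bound. This holds for ABCB1, CROT, SLCO4C1, ZNF737, ABCG2 and ERAP2 between untreated lines and for CROT and ZNF737 between treated lines. With decitabine it holds for MAEL, GCNA, ABCG2 and SYCP3 in KA and for HORMAD1, SYCP3 and MAEL in KS.

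The array of untreated KS replicate 3 stood apart from the other untreated KS arrays. Over the 329 genes that decitabine raised in KS by at least 1 when this array was left out, its value lay a median of 25.1% of the way from the other untreated arrays to the treated ones on the linear scale (95% bootstrap interval 23.6 to 26.6%). Over the 148 genes lowered by at least 1 the share was 33.8% (31.0 to 36.6%). Treated KS replicate 1 lay 14.7% of the way towards untreated KS over 271 raised genes and 19.7% over 147 lowered genes, and the other 10 arrays lay between -13.4 and 10.5% over raised genes. Over lowered genes the other 4 KS arrays lay between -12.5 and -4.64%, and the 6 KA arrays, with only 2 to 9 such genes each, between -13.0 and 22%.

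Comparing untreated KA with untreated KS asks what accompanies drug resistance. The largest difference was in ABCB1, whose product pumps anthracyclines out of the cell: it read 3.39 ± 0.21 in KS and 11.22 ± 0.04 in KA (mean ± SD, n = 3), an at least 227-fold difference (7.83 ± 0.15, adjusted p = 1.16e-12). Its neighbours on chromosome 7q21 were raised with it: 20 of the 24 measured were higher in KA (20 adjusted over the list alone), with a median of 1.41 (adjusted p = 7.63e-25; adjusted p = 0.000543 with an estimated correlation). CROT, a peroxisomal carnitine acyltransferase, read 2.71 in KS and was at least 93.2-fold higher (6.54 ± 0.08), TMEM243 4.35 ± 0.08, ELAPOR2, an endosomal and lysosomal protein, 3.65 ± 0.07, and SLC25A40, a mitochondrial glutathione carrier, 3.35 ± 0.07 higher. In GRCh38.p14 gene order the rise was seen from ELAPOR2, next to GRM3 (0.19, not called), past CDK6 to CASD1, while SGCE and PEG10 beyond it were not called. In KS and KA, GRM3 (2.92 and 3.11) and SGCE (3.21 and 3.32) were not shown to exceed background. PEG10 (3.68 and 3.73) lay little above it, so these genes cannot show where the rise ends. Beyond GRM3, genes further above background were not higher. SEMA3D (4.14 and 4.05), SEMA3E (4.18 and 3.98) and PCLO (4.78 and 4.88) were not called, and SEMA3A differed by -0.89 ± 0.09. On that side the run therefore did not continue past them, though CD36, further out, was 0.87 ± 0.09 higher. The end beyond CASD1 stays open. Windows of 11 neighbouring genes centred on ELAPOR2 to SAMD9 reached a median of 3.20, against at most 0.846 in 100 shuffles of gene order. TP53TG1, a non-coding RNA of the same region, was 4.30 ± 0.14 higher.

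**Figure D1:**
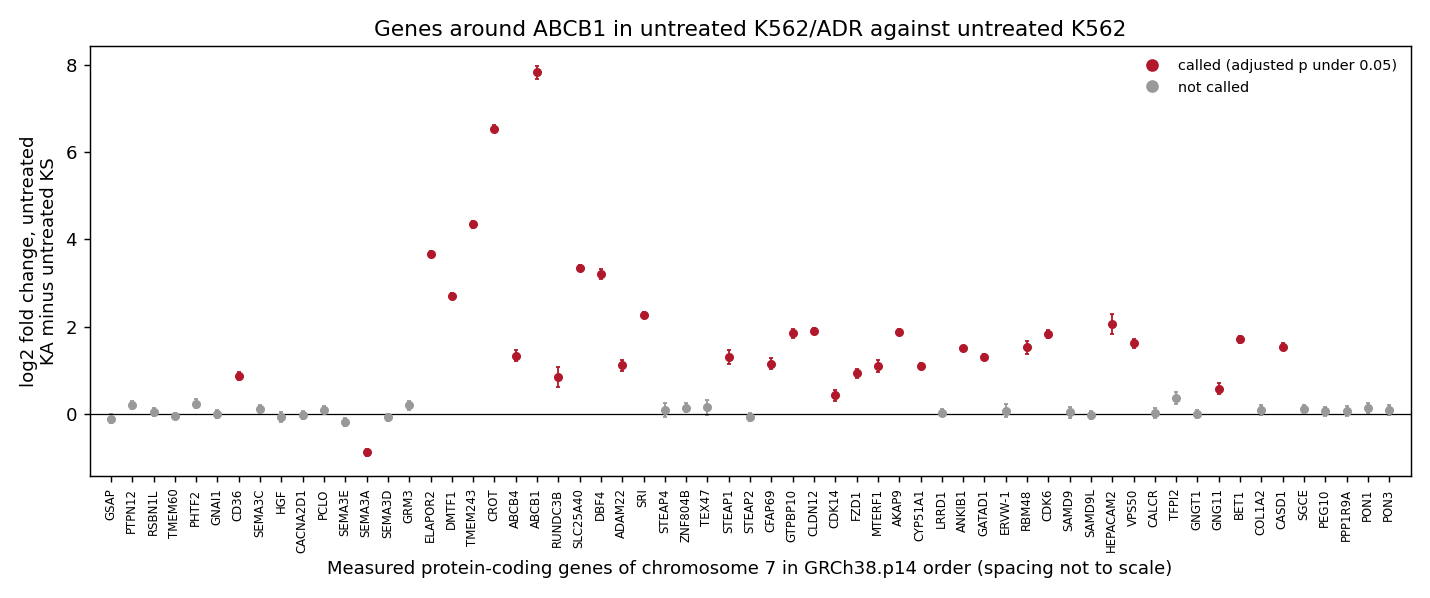
Each point is 1 of 61 protein-coding genes of chromosome 7 in GRCh38.p14 order (horizontal axis, not to scale) with its log2 fold change, untreated KA minus untreated KS (vertical axis; bars, SE from the limma fit over 12 arrays), red where adjusted p is under 0.05. Most called genes form a run from ELAPOR2 (3.65) over ABCB1 (7.83) to CASD1, with genes between them that were not called. Of these, STEAP4 and ZNF804B were not shown to exceed background in either line, so they do not show a break. TEX47 (3.59 in KS and 3.73 in KA) lay little above it. ERVW-1 (4.24 and 4.32) and COL1A2 (4.79 and 4.88) lay further above it and were not called (limma adjusted p = 0.777 and 0.642), so the run has gaps there. CD36 (0.87) and SEMA3A (-0.89), named after their values were seen, were called outside it.

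Other efflux genes did not move as a group. Of 25 measured drug efflux transporters, 5 were higher and 8 lower (6 and 8 adjusted over the list alone). The median was -0.08 and the mean 0.24, the test pointed down, and the list was not called (adjusted p = 0.623). ABCB4, a phospholipid transporter and neighbour of ABCB1, was 1.33 ± 0.12 higher, while ABCG2, an efflux pump for many cytostatics, differed by -1.21 ± 0.10 (adjusted p = 1.91e-06) and ABCA5, a lysosomal transporter, by -0.74 ± 0.09. ABCC1, another anthracycline pump, was 0.22 ± 0.07 higher (adjusted p = 0.0315). The call was lost when any 1 untreated array other than KS replicate 3 was left out. Its adjusted p = 0.0562, 0.0728 and 0.0972 without untreated KA replicates 1, 2 and 3, and 0.0805 and 0.107 without untreated KS replicates 1 and 2.

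Genes for handling the drugs differed in places. Of 18 measured anthracycline targets and metabolic genes, 7 were lower (7 adjusted over the list alone), median -0.17 (adjusted p = 0.0172; adjusted p = 0.253 with an estimated correlation), and -0.08 without untreated KS replicate 3 (adjusted p = 0.0295). CBR1, a carbonyl reductase that turns doxorubicin into its alcohol, differed by -1.98 ± 0.18, TOP2B, a topoisomerase that anthracyclines trap, by -0.60 ± 0.10, RARG, a retinoic acid receptor, by -0.63 ± 0.10 and AKR1C1, an aldo-keto reductase, by -0.46 ± 0.06. TOP2A, the other topoisomerase target, was not called (-0.18 ± 0.08, adjusted p = 0.106). Among 21 measured genes of decitabine uptake and nucleotide metabolism, 3 were higher and 3 lower (3 and 3 adjusted over the list alone), and the list was not called (adjusted p = 0.680). RRM1, a subunit of ribonucleotide reductase, was higher by 0.43 ± 0.07, and SAMHD1, which hydrolyses deoxynucleotide triphosphates, differed by -0.62 ± 0.09. DCK, the kinase that activates decitabine (-0.15, adjusted p = 0.250), CDA, which deaminates it (0.21, adjusted p = 0.149), and SLC29A1, a nucleoside carrier (0.16, adjusted p = 0.140), were not called. Without untreated KS replicate 3, CDA was called (adjusted p = 0.0354). Of 23 measured genes of the DNA methylation machinery, 2 were higher and 1 lower (1 and 1 adjusted over the list alone; list adjusted p = 0.930). These were ZBTB33, a methyl-DNA binding repressor, by 0.43 ± 0.09, TRIM28, a corepressor of KRAB zinc finger proteins, by 0.19 ± 0.06, and HELLS, a chromatin remodeller, by -0.48 ± 0.11. The TRIM28 call (adjusted p = 0.0399) was lost under median centring (0.0565), with the replicate block (0.0667) and without any 1 untreated array (up to 0.121 without untreated KA replicate 1). The methyltransferases DNMT1 (-0.10, adjusted p = 0.278), DNMT3A (0.28, adjusted p = 0.0581) and DNMT3B (-0.02, adjusted p = 0.875) were not called; DNMT3A was called without untreated KS replicate 3 (adjusted p = 0.0105).

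Metabolic and stress lists pointed up in KA. Of 22 measured glycolysis genes, 14 were higher and 1 lower (15 and 1 adjusted over the list alone), median 0.32 (adjusted p = 8.83e-07; adjusted p = 0.382 with an estimated correlation). PDK1, a kinase that inhibits pyruvate dehydrogenase, differed by 0.92 ± 0.08 and ALDOC, an aldolase, by 1.04 ± 0.12. Of 27 genes of the ATF4 and unfolded protein response, 13 were higher and 3 lower (16 and 3 adjusted over the list alone), median 0.33 (adjusted p = 0.000150; adjusted p = 0.439 with an estimated correlation), and 0.19 without untreated KS replicate 3 (adjusted p = 0.00195). DDIT4, an inhibitor of mTOR, was 2.19 ± 0.10 higher, ASNS, asparagine synthetase, 1.56 ± 0.09, and DDIT3, the stress factor CHOP, 1.26 ± 0.12. Of 37 globin and erythroid genes, 12 were higher and 3 lower (14 and 4 adjusted over the list alone), median 0.19 (adjusted p = 0.00172; adjusted p = 0.439 with an estimated correlation), and 0.25 without that array. CA2, carbonic anhydrase II, was 22.6-fold higher, and on the log2 scale BPGM, which makes bisphosphoglycerate, differed by 1.11 ± 0.09 and FECH, which puts iron into haem, by 0.96 ± 0.08. Of 37 cancer-testis and germline genes, 7 were higher and 1 lower (7 and 1 adjusted over the list alone), median 0.10 (adjusted p = 0.0172; adjusted p = 0.330 with an estimated correlation), and 0.16 without that array. SSX1 (4.84 ± 0.09), MAGEC2 (3.40 ± 0.07) and MAGEA1 (4.73 in KS, 7.73 in KA), antigens normally limited to the testis, have near-identical relatives, so which copy was read is uncertain.

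Growth signalling, division, sterol and immune lists pointed down in KA, the immune ones unstably. Of 29 genes that report ERK-MAPK output, 3 were higher and 13 lower (3 and 15 adjusted over the list alone), median -0.29 (adjusted p = 0.00172; adjusted p = 0.430 with an estimated correlation). SPRY2, a feedback inhibitor, differed by -1.47 ± 0.12 and ETV5, an ETS factor, by -1.10 ± 0.09, while JUN, a subunit of AP-1, was 1.02 ± 0.08 higher. Of 29 mitosis genes, 1 was higher and 8 lower (1 and 8 adjusted over the list alone), median -0.14 (adjusted p = 0.00789; adjusted p = 0.686 with an estimated correlation). Cyclin B1 (CCNB1) differed by -0.55 ± 0.07 and the proliferation marker MKI67 by -0.44 ± 0.08. Of 17 cholesterol synthesis genes, 1 was higher and 9 lower (1 and 9 adjusted over the list alone), median -0.28 (adjusted p = 0.00920; adjusted p = 0.514 with an estimated correlation). HMGCS1, HMG-CoA synthase, differed by -0.67 ± 0.08 and IDI1, an isomerase of the pathway, by -0.54 ± 0.09, whereas CYP51A1, a sterol demethylase that lies in the 7q21 run, was 1.09 ± 0.07 higher. Of 43 interferon-stimulated genes, 1 was higher and 9 lower (1 and 9 adjusted over the list alone), median -0.11 (adjusted p = 0.0132; adjusted p = 0.439 with an estimated correlation). The antiviral membrane protein IFITM3 differed by -1.90 ± 0.11 and the nucleotide kinase CMPK2 by -1.24 ± 0.12. Of 16 antigen presentation genes, 6 were lower (7 adjusted over the list alone), median -0.10 (adjusted p = 0.0322; adjusted p = 0.439 with an estimated correlation). Lower were the peptide-trimming enzymes ERAP1 (-0.95 ± 0.09) and ERAP2 (-0.91 ± 0.10). Without untreated KS replicate 3 the interferon median was -0.01 (adjusted p = 0.0790). The antigen presentation median turned to 0.03 without it (adjusted p = 0.136), and that list was also not called without untreated KA replicate 3 (adjusted p = 0.0549).

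The strongest single losses in KA were EREG, epiregulin, a ligand of the EGF receptor (8.87 in KS and 4.58 in KA, -4.29 ± 0.20, adjusted p = 6.83e-09, 19.6-fold lower), and IQGAP2, a cytoskeletal scaffold (-4.27 ± 0.11). SDC2, a cell-surface proteoglycan, differed by -2.69 ± 0.10, SELENOP, the plasma selenium carrier, by -2.65 ± 0.10, and NLRP2, an NLR-family protein, by -3.08 ± 0.11. The KRAB zinc finger genes ZNF730 and ZNF93 differed by -3.13 ± 0.20 and -2.63 ± 0.13, and ZNF737 by -3.00 ± 0.27. SCIN, an actin-severing protein, and SLCO4C1, an organic anion carrier, were 4.30 ± 0.18 and 4.24 ± 0.18 higher. Of the markers of other cell types, 1 of 14 lymphoid (CD3D, a T-cell receptor chain, 2.28 ± 0.09), 1 of 11 epithelial (KRT19, a keratin, 0.56 ± 0.07) and 1 of 14 fibroblast and endothelial genes were higher. Lower were 1 epithelial marker (MUC1, a mucin, -0.77 ± 0.10) and 1 of the fibroblast and endothelial markers, and the lymphoid, epithelial and fibroblast lists were not called (lymphoid and fibroblast adjusted p = 0.307 and 0.683). In all, 4735 genes were called, 2133 higher and 2602 lower, of which 257 were higher and 182 lower by at least 1. Quantile normalization turned the majority to 2610 higher and 2186 lower.

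The effect of decitabine in KA bears on the reversal of resistance. ABCB1 was not called: it read 11.22 before and 11.36 after decitabine (0.15 ± 0.15, adjusted p = 0.567). The largest measured rise was in MAEL, which silences transposons in germ cells, from 2.93 ± 0.19 to 6.07 ± 0.27 (mean ± SD, n = 3; 3.14 ± 0.27, adjusted p = 4.63e-05). GCNA, a germ cell nuclear protein, rose by 2.81 ± 0.35 and TKTL1, a transketolase relative, by 2.76 ± 0.43. The immune genes TNFRSF9, a costimulatory receptor, and C3, the central complement protein, rose by 2.05 ± 0.23 and 1.93 ± 0.33, and the calcium-binding proteins S100P and CALB1 by 1.91 ± 0.15 and 1.90 ± 0.12. The largest falls were in clustered histone genes such as H1-5, a linker histone (9.10 to 7.71, -1.40 ± 0.22). H2AC21 changed by -1.20 ± 0.24, H4C14 and H4C15, which share their values, by -1.07 ± 0.21, H2AC4 by -1.01 ± 0.16 and the linker histone H1-3 by -0.91 ± 0.15. SNORD15A, a small nucleolar RNA, changed by -0.94 ± 0.09.

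Of the 25 efflux transporters, 6 rose and 1 fell (6 and 1 adjusted over the list alone); the median was -0.04, the mean 0.09 and the test pointed up, without a call (adjusted p = 0.474). ABCB4 rose by 1.40 ± 0.12, ABCG2 by 0.46 ± 0.10 (adjusted p = 0.0102) and TAP1, a subunit of the peptide transporter, by 0.77 ± 0.16, and ABCC1 was not called (-0.05, adjusted p = 0.671). Of the 24 neighbours of ABCB1, 8 rose and 1 fell (10 and 2 adjusted over the list alone), median 0.20 (adjusted p = 0.00940; adjusted p = 0.265 with an estimated correlation). RUNDC3B, a RUN-domain protein, changed by 1.56 ± 0.22, CROT by 0.53 ± 0.08 and DMTF1, a cyclin D binding factor, by 0.39 ± 0.07. Of the 23 DNA methylation genes, 1 rose and 2 fell (2 fell adjusted over the list alone; list adjusted p = 0.318), among them MBD3, a member of the NuRD complex (-0.34 ± 0.07). DNMT1 (-0.11, adjusted p = 0.281), DNMT3A (0.17, adjusted p = 0.284) and DNMT3B (-0.02, adjusted p = 0.884) were not called. Of the 21 uptake and nucleotide genes, 2 rose and 2 fell (2 and 2 adjusted over the list alone; list adjusted p = 0.305). Falling were TYMS, thymidylate synthase, by -0.44 ± 0.06 and SLC29A2, a nucleoside carrier, by -0.32 ± 0.07. DCK (-0.02, adjusted p = 0.919), CDA (-0.12, adjusted p = 0.454) and SLC29A1 (0.02, adjusted p = 0.864) were not called.

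In KA the mitosis and stress lists pointed up, and the histone and glycolysis lists down. Of 29 mitosis genes, 17 rose (23 adjusted over the list alone), median 0.32 (adjusted p = 2.88e-11; adjusted p = 0.265 with an estimated correlation). Among them were CDC25C, a phosphatase that starts mitosis (0.65 ± 0.10), cyclin B2 (CCNB2, 0.49 ± 0.07), KIF20A, a mitotic kinesin (0.46 ± 0.07), and TOP2A (0.39 ± 0.08). Of 27 ATF4 and unfolded protein response genes, 14 rose and 1 fell (16 and 1 adjusted over the list alone), median 0.28 (adjusted p = 3.88e-09; adjusted p = 0.265 with an estimated correlation). PHGDH, which starts serine synthesis, changed by 0.72 ± 0.08, and the endoplasmic reticulum genes SDF2L1, HERPUD1 and HSP90B1 by 0.71 ± 0.08, 0.57 ± 0.06 and 0.53 ± 0.06. Of 19 histone genes, 12 fell (1 rose and 15 fell adjusted over the list alone), median -0.46 (adjusted p = 6.28e-09; adjusted p = 0.265 with an estimated correlation). H2BC21 changed by -0.63 ± 0.08 and H1-2 by -0.73 ± 0.12. H3C11, outside this list, rose by 2.08 ± 0.23, and since the clustered histone genes are near copies of one another, which member was read is uncertain. Of 22 glycolysis genes, 1 rose and 13 fell (1 and 14 adjusted over the list alone), median -0.25 (adjusted p = 1.95e-06; adjusted p = 0.297 with an estimated correlation). Pyruvate kinase (PKM) changed by -0.62 ± 0.08, phosphoglycerate kinase (PGK1) by -0.56 ± 0.08 and hexokinase 2 (HK2) by -0.94 ± 0.19.

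Smaller shifts reached immune, erythroid and other lists. Of 43 interferon-stimulated genes, 11 rose (11 adjusted over the list alone), median 0.05 (adjusted p = 0.0202; adjusted p = 0.413 with an estimated correlation). Risers included IRF1, an interferon response factor (0.65 ± 0.08), and PARP14, an ADP-ribosyltransferase (0.79 ± 0.11). Of 16 antigen presentation genes, 6 rose (6 rose and 2 fell adjusted over the list alone), median 0.11 (adjusted p = 0.0328; adjusted p = 0.413 with an estimated correlation). TAPBP, which loads peptides, rose by 0.72 ± 0.08 and ERAP1 by 0.70 ± 0.09. Of 37 globin and erythroid genes, 13 rose and 2 fell (17 and 4 adjusted over the list alone), median 0.16 (adjusted p = 0.00940; adjusted p = 0.413 with an estimated correlation). KEL, a red cell antigen, rose by 0.60 ± 0.09 and UROS, an enzyme of haem synthesis, by 0.48 ± 0.07, and HEMGN, a nuclear protein of haematopoietic cells, changed by -0.50 ± 0.08. Of 28 p53 targets, 8 rose and 1 fell (8 and 1 adjusted over the list alone), median 0.11 (adjusted p = 0.0253; adjusted p = 0.265 with an estimated correlation). TP53INP1, a proapoptotic stress protein, changed by 1.15 ± 0.23. Of 18 imprinted genes, 4 rose (5 adjusted over the list alone), median 0.14 (adjusted p = 0.0253; adjusted p = 0.413 with an estimated correlation). DIRAS3, a Ras-like tumour suppressor, changed by 0.85 ± 0.14 and MEST, a hydrolase-like protein, by 0.73 ± 0.12. Of 32 cytoskeleton and adhesion genes, 6 rose (7 rose and 1 fell adjusted over the list alone), median 0.08 (adjusted p = 0.0229; adjusted p = 0.450 with an estimated correlation). SELPLG, a selectin ligand, changed by 0.92 ± 0.09 and vimentin (VIM) by 0.56 ± 0.06. These last calls rested on single arrays: without untreated KA replicate 3 the antigen presentation, imprinted and cytoskeleton lists gave adjusted p = 0.0836, 0.125 and 0.0511. Antigen presentation gave adjusted p = 0.0529 without treated KA replicate 2, the cytoskeleton list 0.0566 without treated KA replicate 3, and the p53 list 0.0790 without untreated KA replicate 1.

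The 37 cancer-testis and germline genes were not called as a list (7 rose and 2 fell; 10 and 2 adjusted over the list alone; median 0.03, adjusted p = 0.372). DAZL, a germ cell RNA-binding protein (1.40 ± 0.21), and SYCP3, of the meiotic synaptonemal complex (0.89 ± 0.12), rose with MAEL and TKTL1. The ERK-MAPK output list was not called either (1 rose and 4 fell; 1 and 7 adjusted over the list alone; median -0.07, adjusted p = 0.0651), but it passed under quantile normalization (adjusted p = 0.0340) and without treated KA replicate 3 (adjusted p = 0.0494). ETV1, an ETS factor in it, changed by -0.69 ± 0.13. Among markers of other cell types, 1 fibroblast gene of 14 rose, and the lymphoid, epithelial and fibroblast lists were not called (adjusted p = 0.915, 0.318 and 0.915). Decitabine called 2694 genes in KA, 1780 of them raised and 914 lowered, with 86 raised and 5 lowered by at least 1. The count fell to 1653 without treated KA replicate 3, to 1706 without untreated KA replicate 1 and to 1725 without untreated KA replicate 2.

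In KS the largest measured rise with the same exposure was in SLC4A1, the band 3 anion exchanger of red cells, from 5.69 ± 1.54 to 9.31 ± 0.11 (mean ± SD, n = 3; 3.62 ± 0.50, adjusted p = 0.000141). TKTL1 rose by 3.33 ± 0.43, the meiotic protein HORMAD1 by 3.01 ± 0.41 and AQP1, a water channel of red cells, from 7.16 to 10.16. CD226, an adhesion receptor of immune cells, rose by 2.87 ± 0.21, PGLYRP4, which binds bacterial cell walls, by 2.85 ± 0.35, DUSP21, a testis phosphatase, by 2.79 ± 0.34 and GCNA by 2.77 ± 0.35. Most of the largest falls were again in histone genes, with H1-5 at -2.52 ± 0.22 (9.46 to 6.95) and H2AC21 at -2.16 ± 0.24. H2AC20 changed by -2.03 ± 0.23, H4C14 and H4C15 by -2.02 ± 0.21 and H4C2 by -1.96 ± 0.16. EGR1, an immediate early factor, had the third largest fall (11.29 to 9.22, -2.07 ± 0.25), and MIR17HG, the host of a microRNA cluster that drives growth, changed by -1.85 ± 0.16. Untreated KS replicate 3 read 7.45 for SLC4A1 and 6.62 for TKTL1, against 4.98 and 4.63, and 4.67 and 4.39, on the other untreated KS arrays. Without it SLC4A1 rose by 4.51 ± 0.10, TKTL1 by 4.03 ± 0.20, HORMAD1 by 3.73 ± 0.10 and AQP1 by 3.71 ± 0.10.

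Blood cell lists pointed up. Of 37 globin and erythroid genes, 24 rose and 3 fell (25 and 3 adjusted over the list alone), median 0.42 (adjusted p = 1.16e-08; adjusted p = 0.248 with an estimated correlation). Delta globin (HBD) went from 6.12 to 7.32, KEL changed by 0.92 ± 0.09 and PPOX, an enzyme of haem synthesis, by 1.05 ± 0.10. Of 32 myeloid and monocyte genes, 10 rose (10 adjusted over the list alone), median 0.18 (adjusted p = 0.00258; adjusted p = 0.501 with an estimated correlation). LYZ, lysozyme, changed by 2.61 ± 0.34 and TYROBP, a signalling adaptor, by 0.96 ± 0.15; LYZ read 9.57 on untreated KS replicate 3 against 7.77 and 7.86 on the others. Of 25 megakaryocyte genes, 10 rose and 2 fell (10 and 2 adjusted over the list alone), median 0.12 (adjusted p = 0.0304; adjusted p = 0.501 with an estimated correlation). Integrin beta 3 (ITGB3) changed by 2.10 ± 0.24 and TUBB1, the platelet tubulin, by 0.97 ± 0.08. Without untreated KS replicate 3 the medians of these 3 lists were 0.45, 0.26 and 0.17. The megakaryocyte call was lost under quantile normalization (adjusted p = 0.0680) and without treated KS replicate 3 (0.0604), untreated KS replicate 1 (0.05003) or untreated KS replicate 2 (0.0583). Of 32 cytoskeleton and adhesion genes, 12 rose and 1 fell (13 and 3 adjusted over the list alone), median 0.16 (adjusted p = 0.0211; adjusted p = 0.516 with an estimated correlation; 0.0565 without treated KS replicate 1). S100A10, an annexin partner, changed by 1.32 ± 0.15.

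Growth-signalling, histone and stress lists pointed down in KS. Of 29 ERK-MAPK output genes, 2 rose and 18 fell (2 and 18 adjusted over the list alone), median -0.39 (adjusted p = 3.43e-06; adjusted p = 0.248 with an estimated correlation). FOS and FOSL1, subunits of AP-1, changed by -1.73 ± 0.17 and -0.80 ± 0.07, and DUSP1, a MAPK phosphatase, by -1.09 ± 0.09. Of 19 histone genes, 15 fell (15 adjusted over the list alone), median -0.81 (adjusted p = 9.50e-09; adjusted p = 0.281 with an estimated correlation). H2AC8 changed by -1.69 ± 0.14 and H2BC21 by -0.87 ± 0.08. Of 27 ATF4 and unfolded protein response genes, 4 rose and 15 fell (5 and 16 adjusted over the list alone), median -0.27 (adjusted p = 0.00258; adjusted p = 0.501 with an estimated correlation). PSAT1, of serine synthesis, changed by -1.33 ± 0.10, SLC7A11, the cystine carrier, by -1.07 ± 0.13, CHAC1, which degrades glutathione, by -0.96 ± 0.10 and TRIB3, a stress pseudokinase, by -0.87 ± 0.10. Mitosis genes moved up: 17 of 29 rose (17 adjusted over the list alone), median 0.34 (adjusted p = 2.17e-06; adjusted p = 0.473 with an estimated correlation). CDC25C changed by 0.87 ± 0.10 and TOP2A by 0.52 ± 0.08. Of the 23 DNA methylation genes, 2 rose and 11 fell (3 and 12 adjusted over the list alone), median -0.18 (adjusted p = 0.04999; adjusted p = 0.567 with an estimated correlation). DNMT3B changed by -0.45 ± 0.08 (adjusted p = 0.000962) and DNMT1 by -0.28 ± 0.06 (adjusted p = 0.00421). MBD2, a methyl-DNA reader, and SETDB1, a histone methyltransferase, fell by 0.41 each. DNMT3A was not called (0.28, adjusted p = 0.0529; 0.00893 without untreated KS replicate 3). That list call was lost under quantile normalization (adjusted p = 0.152), with the replicate block (0.0518) and without treated KS replicate 2 (0.109) or 3 (0.0715) or untreated KS replicate 1 (0.112) or 2 (0.133), and gave 0.00930 without untreated KS replicate 3.

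Germline, immune and imprinted lists pointed up, though most members were not called. Of 37 cancer-testis and germline genes, 12 rose and 3 fell (14 and 4 adjusted over the list alone), median 0.22 (adjusted p = 0.0109; adjusted p = 0.248 with an estimated correlation). MAEL changed by 2.23 ± 0.27, SYCP3 by 1.25 ± 0.12, SSX1 by 0.78 ± 0.09 and MAGEC2 by 0.63 ± 0.07. Of 16 antigen presentation genes, 6 rose and 1 fell (6 and 1 adjusted over the list alone), median 0.11 (adjusted p = 0.0109; adjusted p = 0.473 with an estimated correlation). PSMB9, an immunoproteasome subunit, changed by 1.87 ± 0.17, TAP1 by 1.50 ± 0.16 and TAPBP by 0.91 ± 0.08. Of 43 interferon-stimulated genes, 13 rose and 3 fell (13 and 3 adjusted over the list alone), median 0.12 (adjusted p = 0.0197; adjusted p = 0.501 with an estimated correlation; 0.0609 without untreated KS replicate 2). LGALS3BP, a secreted galectin ligand, changed by 1.56 ± 0.18 and IFI6, an antiviral protein, by 1.26 ± 0.16. Of 18 imprinted genes, 8 rose and 1 fell (8 and 1 adjusted over the list alone), median 0.15 (adjusted p = 0.0211; adjusted p = 0.481 with an estimated correlation). They include L3MBTL1, a chromatin-compacting protein (0.55 ± 0.11), and GRB10, an adaptor that restrains growth factor receptors (-0.57 ± 0.07). Without untreated KS replicate 3 these 4 lists had medians of 0.24, 0.17, 0.15 and 0.21.

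ABCB1 was not called in KS (0.07 ± 0.15, adjusted p = 0.794), nor was ABCC1 (0.14, adjusted p = 0.147), and ABCG2 rose by 0.91 ± 0.10. Of the 25 efflux transporters, 9 rose and 7 fell (9 and 8 adjusted over the list alone; list adjusted p = 0.383). ABCA5 rose by 0.73 ± 0.09, and ABCF1, a translation factor of the family, changed by -0.50 ± 0.07. Of the 24 neighbours of ABCB1, 5 rose and 1 fell (5 and 1 adjusted over the list alone; median 0.0020, list adjusted p = 0.502). ELAPOR2 changed by 0.71 ± 0.07 and CYP51A1 by -0.57 ± 0.07. Of the 21 uptake and nucleotide genes, 2 rose and 4 fell (2 and 4 adjusted over the list alone; list adjusted p = 0.445). SLC29A2 changed by -0.61 ± 0.07, TK1, thymidine kinase, by 0.43 ± 0.10 and DTYMK, thymidylate kinase, by -0.54 ± 0.10. DCK (0.19, adjusted p = 0.127) and CDA (-0.10, adjusted p = 0.496) were not called, and SLC29A1 passed narrowly (0.24, adjusted p = 0.0249). SLC29A1 lost the call without treated KS replicate 2 (0.0968) or 3 (0.0696) or untreated KS replicate 1 (0.0609) or 2 (0.103). Of the other cell type markers, 1 of 11 epithelial genes rose and 1 fell, 1 of 14 fibroblast and endothelial genes rose (COL1A1, a collagen, 0.52 ± 0.08). The epithelial, fibroblast and lymphoid lists were not called (adjusted p = 0.634, 0.585 and 0.721). In KS 5585 genes were called, 2685 raised and 2900 lowered, of which 250 were raised and 105 lowered by at least 1. Without untreated KS replicate 3 the count was 5775, of which 5120 were among the 5585.

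**Figure D2:**
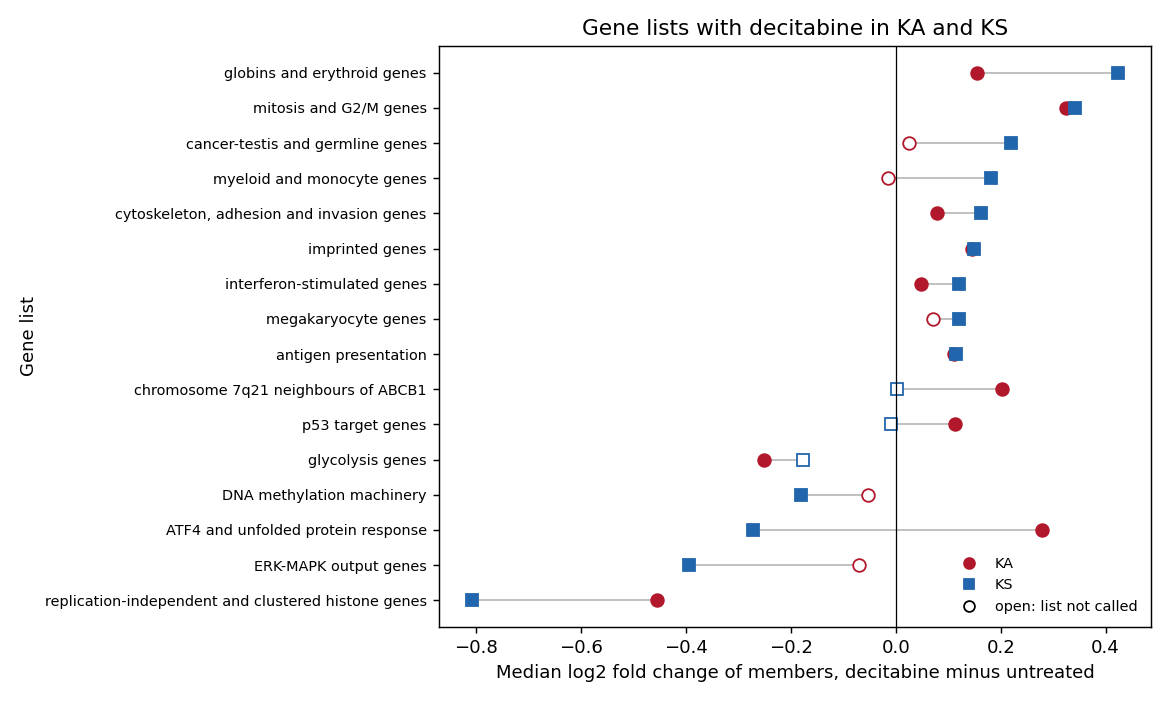
Each line is 1 of 16 gene lists called with decitabine in KA or KS; the horizontal axis is the median log2 fold change of its measured members, decitabine minus untreated (circles KA, squares KS, filled where camera's adjusted p is under 0.05). The ATF4 and unfolded protein response list lies at 0.28 in KA and -0.27 in KS.

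The difference between the lines' responses was tested as an interaction. The clearest was the ATF4 and unfolded protein response list, with a median change of 0.28 in KA and -0.27 in KS. Neither change of the list was called with an estimated correlation. Of its 27 members 16 differed, each with the higher change in KA (21 adjusted over the list alone), with a median difference of 0.65 (adjusted p = 2.81e-18; adjusted p = 0.167 with an estimated correlation). PSAT1 read 8.24 before and 8.31 after decitabine in KA and went from 8.01 to 6.68 in KS (difference 1.40 ± 0.14, adjusted p = 0.000821). PHGDH differed by 0.99 ± 0.11, SDF2L1 by 0.91 ± 0.12 and HERPUD1, an endoplasmic reticulum degradation factor, by 0.89 ± 0.09 (adjusted p = 0.000857). The ERK-MAPK output list also responded differently, with median changes of -0.07 in KA and -0.39 in KS. Of its 29 genes, 10 differed towards KA and 1 towards KS (13 and 1 adjusted over the list alone). The median difference was 0.24 (adjusted p = 1.69e-05, and 0.258 with an estimated correlation), and 0.32 without untreated KS replicate 3. The lines came closer on this list: its median, KA minus KS, was -0.29 untreated and -0.02 treated (not called, camera adjusted p = 0.965). EGR1 differed by 1.81 ± 0.35, FOS by 1.66 ± 0.24 and SPRY4, a feedback inhibitor, by 1.20 ± 0.18.

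The erythroid and myeloid lists responded more in KS, and the megakaryocyte list was not called for a difference (adjusted p = 0.306). The erythroid list had been higher in untreated KA (median 0.19, KA minus KS), and between treated lines it was not called (-0.08, camera adjusted p = 0.655). Only 2 of 32 myeloid genes were called for a difference, against 6.74% of all genes. Of 37 globin and erythroid genes, 1 differed towards KA and 8 towards KS (1 and 13 adjusted over the list alone), median difference -0.27 (adjusted p = 3.69e-07; adjusted p = 0.258 with an estimated correlation). HBD differed by -1.25 ± 0.15 and CPOX, of haem synthesis, by -0.71 ± 0.09; without untreated KS replicate 3 the median was -0.34. Of 32 myeloid genes, 2 differed towards KS (1 adjusted over the list alone), median -0.23 (adjusted p = 0.000737; adjusted p = 0.671 with an estimated correlation), and -0.28 without that array. The histone list fell less in KA: 3 of 19 differed (6 adjusted over the list alone), median 0.24 (adjusted p = 0.00298; adjusted p = 0.750 with an estimated correlation), and 0.32 without that array. H2AC8 differed by 0.92 ± 0.19 and H3-3B by 1.05 ± 0.23; H3-3B was not called without untreated KS replicate 1 (adjusted p = 0.0514). Near ABCB1, RUNDC3B differed by 1.74 ± 0.31 and ABCB4 by 1.48 ± 0.18, and ELAPOR2 by -0.58 ± 0.10. Of the neighbours, 2 of 24 differed towards KA and 1 towards KS (6 and 3 adjusted over the list alone; list adjusted p = 0.398). Of the single genes, CRYAB, a small heat shock protein, differed most (-2.56 ± 0.33, adjusted p = 0.00236; 5.25 to 7.39 in KS, 6.42 to 6.00 in KA). SNORA67, a small nucleolar RNA, differed by 1.70 ± 0.37 (adjusted p = 0.0182; 0.0525 without untreated KS replicate 1), and PGLYRP4 by -2.06 ± 0.49 (adjusted p = 0.0276; lost without 7 of the arrays in turn, up to 0.0749 without untreated KS replicate 1). HPGD, which inactivates prostaglandins, differed by -1.80 ± 0.32 and ZC3H6, a zinc finger protein, by -1.65 ± 0.23.

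**Figure D3:**
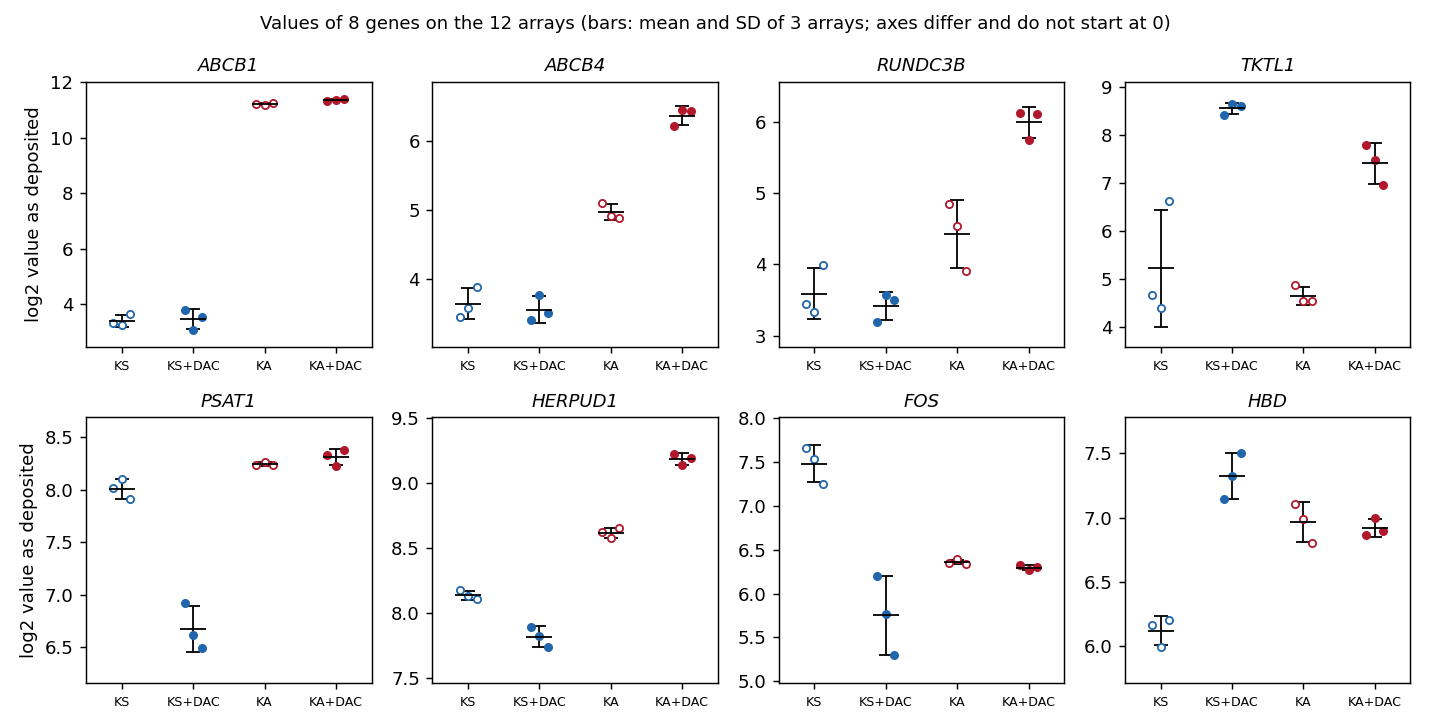
Log2 values (vertical axes, which differ between panels) of 8 genes on the 12 arrays in untreated KS, treated KS, untreated KA and treated KA (horizontal axis); each point is an array and bars give mean and SD of 3 arrays. ABCB1 lies near 11 in both KA groups, PSAT1 and FOS fall in KS, and 1 untreated KS array of TKTL1 reads 6.62.

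No difference was called for ABCB1 (0.08, adjusted p = 0.871), ABCC1 (-0.19, adjusted p = 0.257), ABCG2 (-0.45, adjusted p = 0.0808) or DNMT1 (0.17, adjusted p = 0.283). DNMT3A (-0.10, adjusted p = 0.719), DCK (-0.21, adjusted p = 0.346), CDA (-0.02, adjusted p = 0.954), SLC29A1 (-0.22, adjusted p = 0.240) and TOP2A (-0.14, adjusted p = 0.508) were not called either. DNMT3B differed by 0.43 (adjusted p = 0.0453), a call lost under quantile normalization (0.0713), with the replicate block (0.0677) and without 10 of the arrays in turn, up to 0.112 without untreated KS replicate 1. The cancer-testis list was not called for a difference (2 genes towards KS, SSX1 at -0.80 ± 0.13 and MAGEC2 at -0.57 ± 0.09; adjusted p = 0.0915), but was without untreated KS replicate 3 (adjusted p = 0.0393) and without untreated KA replicate 2 (0.0449). In all, 1241 genes differed, 847 with the higher change in KA (68.3%) and 394 in KS; under quantile normalization the split was 611 to 522 (53.9% higher). Leaving out single arrays gave from 564 without untreated KS replicate 1 to 2049 without untreated KS replicate 3, which shared 1190 of the 1241 genes. It also fell below 800 without untreated KA replicates 1 (695) or 2 (636), treated KA replicates 1 (776), 2 (670) or 3 (711), or treated KS replicates 2 (780) or 3 (676).

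Both lines responded in the same direction for most genes called in both. Across genes, which are not independent replicates, the changes with decitabine in KA and KS correlated at a Pearson r of 0.62 and a Spearman rho of 0.48, and these comparisons share no array. The number raised in both lines was 1138, against 260 expected of independent lists, and 649 were lowered in both, against 144; 40 rose in KA and fell in KS and 12 did the reverse. Of the 1787 genes moved the same way in both, 1305 changed more in KS.

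Whether decitabine turned back the resistant line's expression was asked of the 439 genes that differed by at least 1 between untreated KA and KS. In KA, decitabine moved 71 of them against the difference and 102 further along it. Among the 257 genes higher in KA, 96 rose further (24.8 expected of independent lists) and 11 fell (12.8 expected); among the 182 lower in KA, 60 rose (17.6 expected) and 6 fell (9.03 expected). In 100 simulations all arrays, the untreated KA controls among them, were redrawn with treated KA left unchanged. A mean of 0.01 genes moved against the difference, at most 1. Without any change in KA almost no gene is called, so this count cannot show what the shared arrays add. The covariance of both sets of changes was -0.000372, against -0.00585 in the simulations; the controls are too few to split, so part of the counts may come from the shared untreated KA arrays. The genes turned back lost a median of 36.8% of their difference, and 6 did so by at least 1, named here after their values were seen. These were CALB1 (-2.15 between the lines, 1.90 with decitabine), LYZ (-1.20 and 1.77), ANXA3, an annexin (-1.09 and 1.38), NTS, neurotensin (-1.21 and 1.34), EFHC2 (-1.48 and 1.06) and MIR32, a microRNA (-1.49 and 1.03). This count sets treated KA against untreated KS only. Decitabine also raised LYZ in KS, by more than in KA. Without untreated KS replicate 3 the differences of LYZ (-0.61) and ANXA3 (-0.98) fall under the size of 1 asked here, and those of the others were -1.99 (CALB1), -1.03 (NTS), -1.34 (EFHC2) and -1.71 (MIR32). The count against the difference was 45 without untreated KA replicate 1.

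After decitabine the lines still stood apart. ABCB1 was 7.91 ± 0.15 and CROT 6.95 ± 0.08 higher in treated KA than in treated KS, where they read 3.46 and 2.83. Of ABCB1's neighbours, 21 of 24 were higher (21 adjusted over the list alone), median 1.84 (adjusted p = 2.83e-26; adjusted p = 0.000441 with an estimated correlation). Of the 439 genes, 407 were still called in the same direction, 320 of them by at least 1. Of 27 ATF4 and unfolded protein response genes, 24 were now higher in KA and 1 lower (25 and 1 adjusted over the list alone), median 0.87 (adjusted p = 2.17e-19; adjusted p = 0.0741 with an estimated correlation). ASNS differed by 2.20 ± 0.09, SLC7A11 by 2.14 ± 0.13 and HERPUD1 by 1.37 ± 0.06. TP53TG1 was 4.90 ± 0.14 and TMEM243 4.36 ± 0.08 higher, while IQGAP2 differed by -4.01 ± 0.11, ZNF730 by -3.69 ± 0.20, SDC2 by -3.47 ± 0.10 and ZNF737 by -3.39 ± 0.27. ABCB4 was 2.81 ± 0.12 higher, ABCG2 differed by -1.66 ± 0.10 and ABCC1 was not called (0.03, adjusted p = 0.840). DNMT3B was higher in KA (0.40 ± 0.08, adjusted p = 0.00222) and DCK lower (-0.36 ± 0.09, adjusted p = 0.00752). Of 18 anthracycline genes, 2 were higher and 9 lower (3 and 9 adjusted over the list alone), median -0.18 (adjusted p = 0.0146; adjusted p = 0.128 with an estimated correlation). CBR1 differed by -1.78 ± 0.18 and TOP2A by -0.32 ± 0.08. DNMT1 (0.07, adjusted p = 0.512), DNMT3A (0.17, adjusted p = 0.237), CDA (0.19, adjusted p = 0.188) and SLC29A1 (-0.06, adjusted p = 0.658) were not called. In all, 4977 genes were called, 2777 higher and 2200 lower in KA, with 300 higher and 211 lower by at least 1.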

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

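The tests of other sample splits of the values as they stand and of brightness-matched random lists were planned; the remaining tests of this part, with the splits after removal of shared effects, were chosen only after the results were seen.

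Between the lines, the response to decitabine differed for 1241 genes by the interaction test. The arrays were split after line means and the shared effect of decitabine were removed. Of 100 such splits, only the real 1 gave as many genes, and the highest other gave 442. These splits still mix treated with untreated arrays, and replicates are not known to be separate cultures, so chance is not excluded for this count. Splits of the values as they stand (1 of 100 as large, highest other 1016) decide nothing here, because they mix treated with untreated arrays. For untreated lines (4735 genes), decitabine in KA (2694), decitabine in KS (5585) and treated lines (4977), 10 splits each are too few for a share under 0.05; 1 split, the real one, reached its count and the highest other gave 0 at the same threshold in limma.

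What drew attention in the following is a difference between the lines. List medians differed by 0.65 for ATF4 and unfolded protein response genes, 0.24 for ERK-MAPK output genes, 0.24 for histone genes, -0.27 for globin and erythroid genes and -0.23 for myeloid genes. None of these lists was called for a difference with an estimated correlation. Genes with the higher change in KA were ABCB4 1.48, CHAC1 0.94, DIRAS3 0.80, DNMT3B 0.43, DUSP1 0.78, EGR1 1.81, FOS 1.66, FOSL1 0.63, GRB10 0.54, H1-3 0.80, H1-5 1.12, H2AC20 1.17, H2AC8 0.92, H3-3B 1.05, H4C2 1.20, HERPUD1 0.89, MIR17HG 1.58, MIR32 1.18, PHGDH 0.99, PSAT1 1.40, RUNDC3B 1.74, S100P 0.78, SDF2L1 0.91, SLC7A11 1.15, SNORA67 1.70, SPRY4 1.20 and TRIB3 1.03. Genes with the higher change in KS were ABCA5 -0.61, CD226 -1.51, CPOX -0.71, CRYAB -2.56, ELAPOR2 -0.58, HBD -1.25, HEMGN -0.56, HPGD -1.80, MAGEC2 -0.57, PGLYRP4 -2.06, PSMB9 -1.65, S100A10 -1.18, SNORD15A -0.56, SSX1 -0.80, TUBB1 -0.90 and ZC3H6 -1.65. Several of these calls hang on single arrays. Leaving out 1 array at a time ended the call of H1-5 and H2AC20 in 11 cases each (adjusted p up to 0.111 without treated KS replicate 2 and 0.114 without treated KS replicate 3). It ended those of DNMT3B, DIRAS3 and H1-3 in 10 each (up to 0.112, 0.0886 and 0.0973, without untreated KS replicate 1), of MIR32 in 9 (0.112, same array), of S100P in 8 (0.0980, without treated KA replicate 3), of PGLYRP4 in 7 (0.0749, without untreated KS replicate 1) and of SNORD15A in 6 (0.0712, without untreated KA replicate 2). ABCA5 (0.0530, without treated KA replicate 2), H3-3B and SNORA67 (0.0514 and 0.0525, without untreated KS replicate 1) each lost it in 1.

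Calls were also made among clusters outside the comparisons, those without exactly 1 gene name. Of 13837 such clusters, 1306 were called between untreated lines, 124 with decitabine in KA and 1614 with decitabine in KS. These are smaller shares than among the 18417 named genes, of which 4735, 2694 and 5585 were called. What the unnamed clusters read was not examined.

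The neighbours of ABCB1 were higher in KA as a run. Probes shared with ABCB1 are argued against by the 23 members outside the ABC family, with a median of 1.50 (0.92 to 2.27). Methylation that this dose lifts is argued against, for the list as a whole, by its median of 0.0020 with decitabine in KS (-0.11 to 0.12). Single members did rise there: ELAPOR2 by 0.71, DMTF1 by 0.66, AKAP9 by 0.54, TMEM243 by 0.42 and ANKIB1 by 0.33. CYP51A1 changed by -0.57. The rises were smaller than the same genes' differences between untreated lines (3.65, 2.71, 1.87, 4.35 and 1.50), so for these genes methylation stays open in part. Methylation itself was not measured. Extra copies of the region, a hypothesis, need every well-expressed member to be higher, and 100% of the 10 members above the median level in untreated KS were. Their changes ran from 0.92 to 3.65, a range that 1 copy number shared by all would not give on its own. DNA copy number was not measured here, and selection in adriamycin stays untested.

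The ATF4 and unfolded protein response list moved apart between the lines. Scaling that acts by brightness is argued against by 10000 matched random lists, whose highest median was 0.29 against 0.65. A single aberrant array is argued against by a median of at least 0.58 without any 1 array. For amino acid shortage, the 7 chaperone members were taken as genes that do not answer it, which was not tested here, so they cannot decide. They differed by a median of 0.60 (0.28 to 0.89 over resampled members), and by 0.50 (0.25 to 0.79) without HERPUD1, a degradation factor. Of the 7, HSP90B1, DNAJB9 and PDIA4 were not called for a difference (adjusted p = 0.0691, 0.319 and 0.0773). Amino acid shortage stays open for all list members. Adriamycin in the medium of KA and other differences between the cultures stay open and untested.

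Untreated KS replicate 3 lay towards treated KS, by 33.8% over genes that fell (31.0 to 36.6%) and 25.1% over genes that rose (23.6 to 26.6%). RNA or cells of treated KS in that sample stay open: a mixture would bring 1 share, these intervals do not overlap, and how linear the readings are was not tested. RNA or cells of KA are argued against by a share of 0.62% (0.11 to 1.45%) over 29 genes higher in KA by at least 3. Higher background or another scale is argued against by random lists matched on level, whose highest median deviation was 0.085 against 0.46. Whether that culture itself met the drug was not tested.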

How the results depend on the processing

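The tests with each array left out of the list tests, with both KS arrays that stand apart left out, and with HERPUD1 left out of the chaperones, were chosen only after the results were seen; the others were planned.

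Asking also for a change of at least 1 left 439 genes between untreated lines, 91 with decitabine in KA, 355 in KS, 87 for the difference and 511 between treated lines. For decitabine in KA, array weights gave 4417 genes and adjusted p under 0.01 gave 1180. Leaving out single arrays gave 1653 (without treated KA replicate 3) to 2002 (without untreated KA replicate 3).

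For the difference, leaving out genes under the 50th percentile gave 2002 genes, trend and robust variance 1918, array weights 2288 and adjusted p under 0.01 226. Leaving out single arrays gave 564 (without untreated KS replicate 1) to 2049 (without untreated KS replicate 3), and leaving out the latter with treated KS replicate 1 gave 2035. With the replicate number as a replicate block it gave 778, though same-number arrays correlated no better than others, at -0.26 to 0.19 over 18 pairs. The count moved against the line difference in KA was 45 (without untreated KA replicate 1) to 74 (without untreated KS replicate 1).

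With a correlation estimated for each list, camera called 1 list between untreated lines, 1 between treated lines, and 0, 0 and 0 with decitabine in KA, in KS and for the difference (unadjusted p under 0.05 in 5, 4 and 3 lists). With fry 17 lists were called between untreated lines, 22 in KS, 3 for the difference and 16 between treated lines.

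Some genes picked by the naming rules lost their call when 1 array was left out. These were 4 of 72 called between untreated lines, 11 of 78 with decitabine in KA and 4 of 84 in KS. For the difference they were 14 of 36, and between treated lines 3 of 71. Under another setting 4, 4, 3, 10 and 1 lost it, in the same order. No called named gene changed direction under any alternative. Among uncalled ones 7 values near 0 did. ABCB1 ranged from -0.092 to 0.271 in KS and -0.125 to 0.238 for the difference with single arrays left out, and ABCC1 between treated lines from -0.0131 to 0.0608. In KA, DCK ranged from -0.0811 to 0.0423 and DNMT3B from -0.0994 to 0.0390. Between untreated lines DNMT3B ranged from -0.0603 to 0.0285, with 0.0361 under quantile normalization and 0.000793 with array weights. The CDA difference ranged from -0.110 to 0.0832, with 0.0135 under quantile normalization and 0.00831 under median centring. The counts between untreated lines (3824 to 4878 with single arrays left out), with decitabine in KS (4535 to 5775) and between treated lines (4180 to 4508) moved little. Asking for smaller p or larger changes lowers counts by construction; for the other settings the cause was not tested. The values carry no background measure here, so what signal over background limits was not analysed here.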

Other observations

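The gene-order runs, the counts by RNA class and the list tests with 1 or 2 arrays left out were chosen only after the results were seen; the other list tests were planned.

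Some runs of neighbouring zinc finger genes of chromosome 19 (GRCh38.p14 order) were lower in untreated KA. Of the 237 zinc finger genes measured there 85 were lower and 12 higher, median -0.21, against 48 lower and 48 higher of 257 elsewhere. Windows of 11 genes reached -0.93 from ZNF253 to ZNF737, -0.94 from ZNF790 to ZNF527 and -0.58 from VN1R1 to ZNF134, against a lowest value of -0.57 in 100 shuffles. Decitabine raised 28 and lowered 4 of the 237 in KA, against 26 and 7 of the 257 elsewhere, and raised 69 and lowered 13 in KS, against 46 and 34. Lower windows on other chromosomes ran from SLC35A3 to SLC30A7 (-0.59) and DIXDC1 to IL18 (-0.74), and single ones centred on TMEM212 (-0.61), MRE11 (-0.67) and ATP7B (-0.67).

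With decitabine, runs of lower genes lay among the histone genes of chromosome 6: H2AC4 to H4C6 (-0.52) and a window at H2AC15 (-0.49) in KA, and H4C2 to H4C7 (-1.09) and H2AC15 to H3C12 (-0.73) in KS. Of 57 replication-dependent histone genes, 30 fell and 4 rose in KA, and 40 fell and 7 rose in KS. Of 195 small nucleolar and nuclear RNAs, 57 were lower and 8 higher in untreated KA; decitabine lowered 21 and raised 2 in KA, and lowered 69 and raised 21 in KS.

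Between treated lines, glycolysis (median 0.16, adjusted p = 0.00147; adjusted p = 0.542 with an estimated correlation), antigen presentation (-0.14, adjusted p = 0.00228; adjusted p = 0.263 with an estimated correlation) and interferon genes (-0.14, adjusted p = 0.00634; adjusted p = 0.473 with an estimated correlation) were called. So were mitosis (-0.19, adjusted p = 0.00650; adjusted p = 0.728 with an estimated correlation), p53 (0.17, adjusted p = 0.0250; adjusted p = 0.263 with an estimated correlation) and cholesterol genes (-0.19, adjusted p = 0.0365; adjusted p = 0.728 with an estimated correlation). The cholesterol call was lost without treated KA replicate 2 (adjusted p = 0.106) or 3 (0.0675) or treated KS replicate 1 (0.0798), and the p53 call without treated KS replicate 2 (0.0603). Histones (0.276) were called without treated KS replicate 1 (0.00680), and G1/S genes (0.131) under quantile normalization (0.0368) and without treated KA replicate 1 (0.0437).

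With decitabine, these lists were not called in KA and KS: G1/S genes (adjusted p = 0.263 and 0.502), cyclin-dependent kinase inhibitors (0.901 and 0.585), BCL2 family (0.0995 and 0.585), glutathione and NRF2 targets (0.272 and 0.585), MAPK components (0.614 and 0.991), cholesterol genes (0.0651 and 0.0981) and anthracycline genes (0.388 and 0.502). Glycolysis genes were not called in KS (0.0743) unless treated KS replicate 1 was left out (0.0149), and cholesterol genes were called in KA without untreated KA replicate 1 (0.0151) or treated KA replicate 1 (0.0102).

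Between untreated lines, the lists of p53 targets (adjusted p = 0.175), G1/S genes (0.149), cyclin-dependent kinase inhibitors (0.647), BCL2 family (0.623), glutathione and NRF2 targets (0.843), MAPK components (0.678), imprinted genes (0.214), histones (0.194), cytoskeleton (0.799), megakaryocyte (0.484) and myeloid genes (0.209) were not called. Histones were called when untreated KS replicate 3 and treated KS replicate 1 were both left out (0.0318).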
